A study of Nuphar advena with 32 samples.

How the data were processed

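RNA of 8 tissues of Nuphar advena was measured on 16 custom Agilent arrays with 2 dyes each, which gave 32 samples, 4 per tissue. The arrays carried 10807 features: 544 controls and 10263 probes for 6220 transcripts, of which 4043 had 2 probes and 2177 had 1. Per the labels, the tissues were leaf, outer tepal, inner tepal, stamen, carpel, young fruit, pre-microsporangial bud and pre-meiotic bud, and each array paired 2 tissues in an interwoven loop with the dyes alternating. Samples were grouped by tissue and replicate number as the labels give them.

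Per the file headers, the intensity values were read from the scans by Agilent Feature Extraction 9.1.3.1 or 9.5.1.1, which gave mean pixel signals, local backgrounds, calls of well above background (2.6 standard deviations) and a processed signal after subtraction of a fitted background and a dye normalization. The deposited log2 values, given for each probe and channel, were normalized by the authors over all channels with limma, per the submitters' processing notes, with no version or steps stated. Its column medians ran from 7.303 to 7.488 with interquartile ranges of 2.5 to 2.71, on one common scale, and each column correlated at 0.969 or more with its own channel. Over the samples the median signal ran from 111.5 to 524.9, and 52% to 98.2% of probes were well above background.

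Counts and changes were computed from the scanner intensities with limma 3.58.1 and statmod 1.5.0 in R 4.3.3, with jsonlite 2.0.0 and version 1.17.8 of data.table. Mean signals were corrected for the median local background by the normexp method with an offset of 50. Dye effects were removed by loess within arrays and scale differences by Aquantile between arrays, with control spots and spots marked as uneven at weight 0. From 0 to 859 spots were left out per array, the most on the array of stamen 3 and pre-microsporangial bud 3. Probes of a transcript were averaged. A transcript was kept if at least 1 of its probes was well above background in 3 or more of the 4 samples of a tissue, which left out 1204 as too dim and kept 5016, of which 4841 had a value in all 32 samples.

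Separate channels were fitted by generalized least squares with an intraspot correlation of 0.353 and the dye as a covariate, followed by empirical Bayes moderation. The p-values were adjusted by Benjamini and Hochberg over all kept transcripts, with a threshold of 0.05. Each tissue was compared with the mean of the other 7, and 5 pairs of tissues were compared: inner with outer tepal, stamen with inner tepal, carpel with stamen, young fruit with carpel, and pre-meiotic with pre-microsporangial bud. A moderated F test asked for any difference among the 8 tissues. Lists of genes were tested by camera of limma with a preset correlation of 0.01 between genes and, as an alternative, with an estimated correlation, and adjusted over 14 lists and 13 comparisons.

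Names and descriptions came from the Arabidopsis match recorded for the array. Of the 6220 transcripts, 4006 had such a match, to 3302 different genes, and 3317 had a description that names a function. Lists were fixed by symbols, Arabidopsis codes and words in the description. The 14 lists were floral organ identity and meristem regulators, photosynthesis, pollen, tapetum and anther wall, flavonoid and phenylpropanoid metabolism, carotenoid and terpenoid metabolism, cell division, DNA replication and chromatin, ribosomal proteins, cell wall, lipid transfer, cutin and wax, seed, embryo and storage, heat shock and chaperones, defence and wounding, auxin, and starch and sucrose. For leaves and for the 5 pairs, the transcripts named were the 10 largest and 10 smallest changes past the threshold, with samples that did not overlap those of the other tissue, or, for a tissue against the other 7, lay beyond the median of every other tissue. They also had to be well above background in 3 of 4 samples of the higher tissue and to have a named function, with 1 transcript per gene name. For the other 7 tissues the 6 largest and 4 smallest were taken, and for every list past its threshold up to 4 members, with every measured member of the floral list. Of the 448 named results the text prints a part, and the 280 named only as list members entered the counts of samples on the stated side.

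Alternatives were the processed signals of Feature Extraction, median centring, no normalization between arrays, quantile normalization over all channels, other filters, log ratios of the 16 arrays, no dye covariate, no correlation within arrays, replicate or slide as a block, the brightest probe per transcript, the deposited table, only the samples of a pair, and each sample of the compared tissues left out in turn. Scan day as a block and 2 further sets of samples left out were added after the data were seen. The calls were checked by 100 permutations of the tissue labels, and for pairs by all 35 splits of 8 samples into 4 and 4. The code was tested on simulated data. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.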

Results

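Leaves, outer tepals, inner tepals, stamens, carpels, young fruits and 2 bud stages of the water lily Nuphar advena differed in 3174 (63.3%) of the 5016 transcripts well above background in at least 3 of the 4 samples of a tissue, and in 1525 with log ratios of the 16 arrays. Transcripts are named by the Arabidopsis gene recorded as their match on the array, and the function given is that of the Arabidopsis gene or its family. Changes are log2 differences between tissue means with their standard error, from 4 samples per tissue, or 3 where a spot was left out. Transcripts called higher or lower had a limma adjusted p under 0.05 over all 5016 transcripts. The p-values measure the spread between these samples, which the labels describe only as taken from wild populations. Nothing in the labels says whether the 4 samples of a tissue came from separate plants. The tissues, comparisons, gene lists and rules for naming transcripts were chosen before the data were examined. The largest changes were named only where the samples of a pair did not overlap or, against the other 7 tissues, lay beyond the median of every other tissue, so the samples on the stated side are counted for transcripts named only as members of a list, 257 of 280 with all 4 samples. These too had passed the test in the same samples, so the counts describe the calls and are no separate support.

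Most transcripts, 3595, were well above background in all 8 tissues, 231 in only 1 and 1204 in none. Leaves held 78 of the 231, pre-meiotic buds 68, and pre-microsporangial buds, which precede the pollen sacs, 29. Counts were 4610 in leaves, 4181 in outer and 4108 in inner tepals, 4138 in stamens, 4508 in carpels, 4284 in young fruits, 4360 in pre-microsporangial buds (2870 with all 4 samples required) and 4727 in pre-meiotic buds. Leaf samples had 65% to 95.8% of probes well above background, so the counts need not reflect tissue content. The median of the 28 tissue pairs was 1039.5 differing transcripts, and 260.5 with log ratios. Outer tepals and stamens differed in 72 transcripts, leaves and pre-meiotic buds in 143, and inner tepals and pre-microsporangial buds in 2223. Tissue means correlated at 0.981 between inner and outer tepals, 0.966 between outer tepals and stamens, and 0.781 between inner tepals and pre-microsporangial buds.

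**Figure D1:**
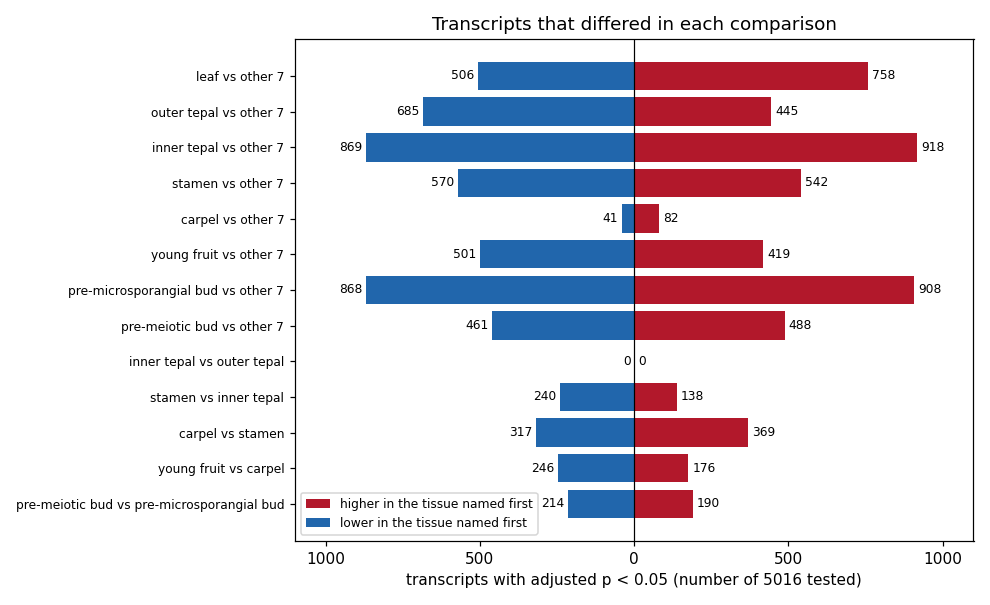
Number of the 5016 tested transcripts with adjusted p under 0.05 in each of the 13 comparisons (horizontal axis, number of transcripts, with those higher in the tissue named first to the right and those lower to the left). Inner tepals had 918 higher and 869 lower transcripts against the other 7 tissues, and 0 against outer tepals.

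The first principal component, 39.7% of the variance, separated tepals and stamens from leaves and from all buds but pre-meiotic bud 3, and the second held 11.7%. In 7 libraries the correlation with another tissue was higher than with their own. Outer tepal 1 correlated at 0.887 with the other outer tepals, at 0.945 with the stamens and at 0.979 with stamen 1. Its AGAMOUS value was 12.68, against 6.81, 7.92 and 6.62 in the other outer tepals. Outer tepal 3 correlated at 0.938 with the other outer tepals and at 0.977 with the inner tepals, and inner tepal 4 at 0.941 with the other inner tepals and at 0.973 with the outer tepals. Pre-meiotic bud 3 correlated at 0.857 with the other pre-meiotic buds and at 0.881 with the stamens. Stamen 1 correlated at 0.928 with the other stamens and at 0.937 with the outer tepals. The other 2 lay near the other bud stage: pre-microsporangial bud 3 at 0.958 with its own and 0.961 with the pre-meiotic buds, and pre-meiotic bud 1 at 0.941 with its own and 0.963 with the pre-microsporangial buds. All 32 samples were kept in the counts given below, and for the 13 comparisons the refits without single libraries of the compared tissues stand beside them where they differ by more than 1.5 times. The counts of other tissue pairs, such as 72 for outer tepals and stamens, were not refitted without any library.

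**Figure D2:**
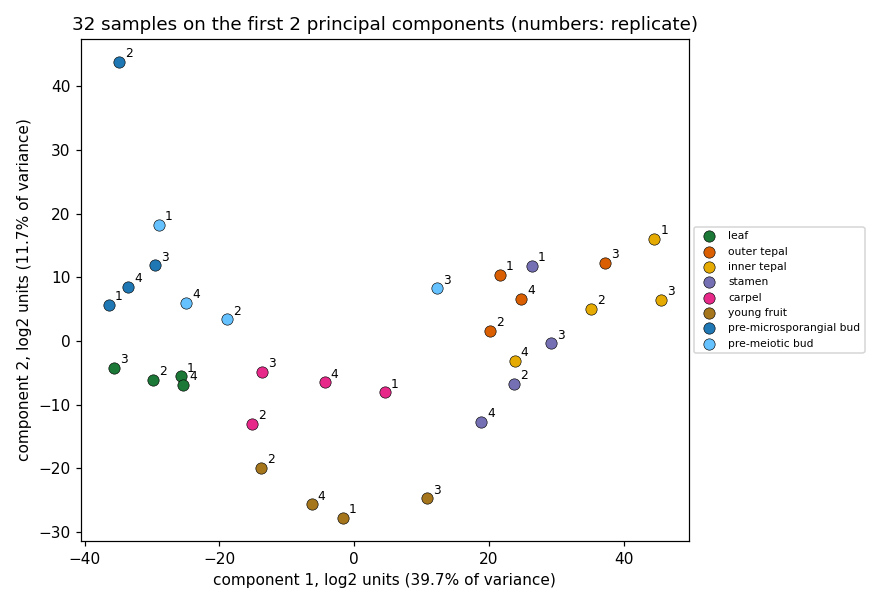
The 32 samples on the first 2 principal components of the tested transcripts (axes in log2 units, 39.7% and 11.7% of the variance, numbers are replicates). Outer tepal 1 lies beside stamen 1, inner tepal 4 lies near the stamens, and pre-meiotic bud 3 lies away from the other buds.

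Matches of AGAMOUS, PISTILLATA, APETALA3 and SEPALLATA1, which specify floral organs in Arabidopsis, each differed among the 8 tissues (limma adjusted p of at most 0.001), and values are mean normalized log2 intensity and standard deviation of 4 samples. AGAMOUS, which specifies stamens and carpels, had 12.32 ± 1.01 in stamens, 11.44 ± 0.68 in carpels, 9.09 ± 0.21 in young fruits, 7.83 ± 0.73 in inner tepals and 6.98 ± 1.1 in leaves. In outer tepals it was 8.51 ± 2.84, with outer tepal 1 at 12.68. The PISTILLATA match nad_3_353627, a petal and stamen identity gene, had 13.99 ± 0.87 in outer tepals, 14.58 ± 0.16 in inner tepals and 13.63 ± 0.69 in stamens, against 10.44 ± 1.71 in carpels and 8.07 ± 0.43 in leaves. A second PISTILLATA match, nad_3_353295, had 6.34 ± 0.24 in leaves and 7.54 ± 1.04 in pre-meiotic buds. APETALA3, the partner of PISTILLATA, had 11.07 ± 0.61, 10.99 ± 0.39 and 11.33 ± 0.61 in outer tepals, inner tepals and stamens and 6.96 ± 0.39 in leaves (nad_3_358723). A second APETALA3 match, nad_3_356264, reached 9.52 ± 0.59 in inner tepals. The SEPALLATA1 match nad_3_356714 had 6.73 ± 0.49 in leaves, 10.53 ± 0.92 in pre-microsporangial buds and 12.62 ± 0.37 in inner tepals, and the match nad_3_353945 had 7.38 ± 0.42, 11.57 ± 0.56 and 12.89 ± 0.4.

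AGL6 had 10.04 ± 0.42 in carpels, 9.81 ± 0.9 in outer tepals, 8.16 ± 0.39 in stamens and 6.84 ± 1.05 in leaves. APETALA1, a meristem and sepal gene, had 8.7 ± 0.26 in pre-microsporangial buds, 8.0 ± 0.32 in leaves and 6.6 ± 0.1 in young fruits. APETALA2 and SPL7 did not pass the test for any difference among tissues (limma adjusted p = 0.16 and 0.52), with 7.16 ± 0.3 and 7.26 ± 0.16 in inner tepals. The list of floral organ identity and meristem regulators held 8 squamosa promoter-binding (SPL) transcripts, matched by the word squamosa, and stress enhanced protein 1, a chloroplast protein that shares the symbol SEP1. SPL9, a regulator of the change from juvenile to adult growth, had 10.24 ± 0.26 in pre-microsporangial buds and 9.95 ± 0.36 in leaves, against 7.55 ± 0.49 in stamens. The YABBY match nad_3_353063 had 10.06 ± 0.77 in outer tepals and 6.39 ± 0.19 in young fruits.

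**Figure D3:**
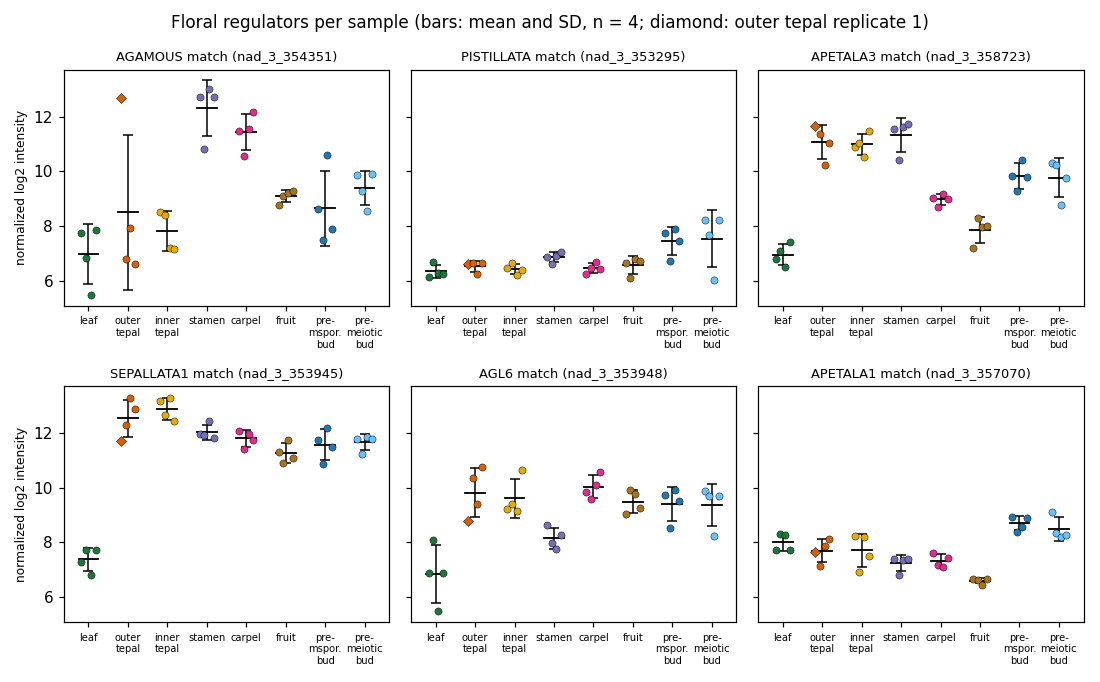
Normalized log2 intensity (vertical axis) of 6 floral regulator transcripts in the 8 tissues, with samples as points, the mean and standard deviation of 4 samples as bars, and outer tepal 1 as a diamond. AGAMOUS averaged 12.32 ± 1.01 in stamens and 6.98 ± 1.1 in leaves, and outer tepal 1 lay at 12.68. The PISTILLATA panel shows the dimmer match, nad_3_353295.

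In leaves, several histones and TUA6 rose, and 8 MADS-box floral regulators fell. Histone H3 rose by 3.3 ± 0.52, 2 histone H4 transcripts by 3.1 ± 0.47 and 2.97 ± 0.51, and the tubulin TUA6, a subunit of microtubules, by 3.23 ± 0.56 (adjusted p from 4.0e-05 to 1.4e-04). They were among the 55 of 95 measured members that rose, beside 1 that fell (57 and 1 adjusted over the list alone, median 0.56) of the cell division, DNA replication and chromatin list (adjusted p = 7.3e-15, and adjusted p = 0.304 with an estimated correlation).

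Both SEPALLATA1 transcripts fell in leaves (-4.57 ± 0.25 and -4.49 ± 0.21), as did PISTILLATA (-3.96 ± 0.4, and -0.56 ± 0.2 for nad_3_353295, well above background in 2 of 4 leaves) and APETALA3 (-3.18 ± 0.24 and -1.75 ± 0.28), with adjusted p from 2.0e-14 to 0.037. AGAMOUS (-3.09 ± 0.6) and AGL6 (-2.54 ± 0.35) fell (adjusted p from 9.8e-06 to 4.5e-04). In contrast, 7 SPL transcripts rose, from 0.24 ± 0.09 to 2.86 ± 0.44, with SPL12 the highest and SPL11 the lowest (adjusted p from 2.2e-08 to 0.036). AINTEGUMENTA, a growth regulator of young organs (0.83 ± 0.09), its relative nad_3_356131 (0.68 ± 0.19) and 2 YABBY transcripts (0.91 ± 0.25 and 0.32 ± 0.1) rose (adjusted p from 4.1e-07 to 0.018). For the floral list as a whole 11 members rose and 8 fell, the median log2 change was 0.24 and the mean -0.40, and the camera test of limma did not pass (adjusted p = 0.731).

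The leaf transcripts of the cell wall list shifted up (adjusted p = 0.00229, and adjusted p = 0.349 with an estimated correlation). A family 1 glycosyl hydrolase (3.05 ± 0.56) and a cellulose synthase family member (1.96 ± 0.37) were among the 18 of 66 measured members that rose, beside 1 that fell (22 and 2 adjusted over the list alone, median 0.28). Lipid transfer, cutin and wax transcripts shifted up (adjusted p = 0.00752, and adjusted p = 0.489 with an estimated correlation). A lipid transfer protein (2.19 ± 0.28) and 3 GDSL lipases (from 1.64 ± 0.51 to 1.9 ± 0.49) were among the 9 of 31 measured members that rose, beside 0 that fell (10 and 1 adjusted over the list alone, median 0.62). Ribosomal proteins shifted up (adjusted p = 0.00353, and adjusted p = 0.82 with an estimated correlation). RPS15aF (0.94 ± 0.23) and RPL5B (0.88 ± 0.23) were among the 21 of 123 measured members that rose, beside 5 that fell (19 and 4 adjusted over the list alone, median 0.26). Starch and sucrose transcripts shifted down (adjusted p = 0.0326, and adjusted p = 0.365 with an estimated correlation). Starch branching enzyme (-1.43 ± 0.26) and starch phosphorylase (-1.25 ± 0.24) were among the 10 of 22 measured members that fell, beside 3 that rose (12 and 5 adjusted over the list alone, median -0.33), while 2 sucrose synthases rose (1.34 ± 0.27 and 1.14 ± 0.28). Photosynthesis transcripts did not shift in leaves against the mean of the other 7 tissues (limma adjusted p = 0.548), with 1 of 19 measured members higher and 2 lower.

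Altogether 1264 transcripts differed, 758 higher and 506 lower, of which 247 and 97 by at least 2-fold, and 35 of 36 transcripts named only as list members had all 4 samples on the stated side. Without leaf 3 the count was 620, with log ratios 599, and without normalization between arrays 766 were higher and 312 lower.

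In outer tepals, light-harvesting proteins, TPS10, PISTILLATA and APETALA3 rose, and several histones and SPL transcripts fell. Photosynthesis transcripts shifted up (adjusted p = 1.5e-04, and adjusted p = 0.318 with an estimated correlation). Light-harvesting chlorophyll protein LHB1B1 (3.56 ± 0.86), photosystem I subunit II (3.16 ± 0.68), the LHCI type III protein (3.09 ± 0.76) and the electron carrier ferredoxin (2.82 ± 0.51) were among the 9 of 19 measured members that rose, beside 0 that fell (9 and 1 adjusted over the list alone, median 0.56). Outer tepal 1 did not show this: its LHCI type III value was 6.22, against 13.78, 13.51 and 13.78 in the other outer tepals. Carotenoid and terpenoid transcripts shifted up (adjusted p = 0.00196, and adjusted p = 0.318 with an estimated correlation). The monoterpene synthase TPS10 (3.24 ± 0.63), a second myrcene/ocimene synthase (2.93 ± 0.55) and the lycopene epsilon and beta cyclases of carotenoid synthesis (0.78 ± 0.13 and 0.57 ± 0.11) were among the 7 of 15 measured members that rose, beside 0 that fell (8 and 0 adjusted over the list alone, median 0.48). Outer tepal 1 was off the stated side in both terpene synthases, with TPS10 at 11.12, against 15.44, 15.44 and 15.16. Cell division transcripts shifted down (adjusted p = 7.7e-10, and adjusted p = 0.318 with an estimated correlation). Histones H3 (-2.74 ± 0.52), H4 (-2.67 ± 0.47) and H2A (-2.36 ± 0.38) and TUA6 (-2.4 ± 0.56) were among the 47 of 95 measured members that fell, beside 2 that rose (53 and 2 adjusted over the list alone, median -0.41).

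Of 23 measured floral regulators in outer tepals 6 rose, 7 fell and 10 did not pass, and the list as a whole did not pass (limma adjusted p = 0.902). PISTILLATA (2.75 ± 0.4), APETALA3 (1.67 ± 0.24), SEPALLATA1 (1.36 ± 0.25 and 1.33 ± 0.21) and the YABBY match nad_3_353063 (0.87 ± 0.25) rose (adjusted p from 6.0e-05 to 0.012). A set of 6 SPL transcripts fell, from -1.52 ± 0.44 to -0.85 ± 0.17, with SPL12 the lowest, and AINTEGUMENTA fell (-0.33 ± 0.09), with adjusted p from 2.1e-04 to 0.014. Of 4 outer tepals, only 1 was well above background in AINTEGUMENTA and 2 in the SPL transcripts nad_3_354009 and nad_3_358481, so that the size of these falls is uncertain. Ribosomal proteins shifted down (adjusted p = 0.00556, and adjusted p = 0.82 with an estimated correlation). RPL36aB (-1.1 ± 0.3) was among the 24 of 123 measured members that fell, beside 8 that rose (32 and 12 adjusted over the list alone, median -0.34), and L35 (1.41 ± 0.22) and S6 (1.14 ± 0.17) rose. In total 1130 transcripts differed, 445 higher and 685 lower, and 21 of 29 transcripts named only as list members had all 4 samples on the stated side, with outer tepal 1 off it in the other 8. On the first scan day, whose only outer tepal was outer tepal 1, 2 of the 4 lists that passed had the same direction. The count was 646 without outer tepal 3, 714 without outer tepal 4, 683 without outer tepal 3 and inner tepal 4, and 264 with log ratios. Median centring in place of loess gave 222 higher and 554 lower.

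**Figure D4:**
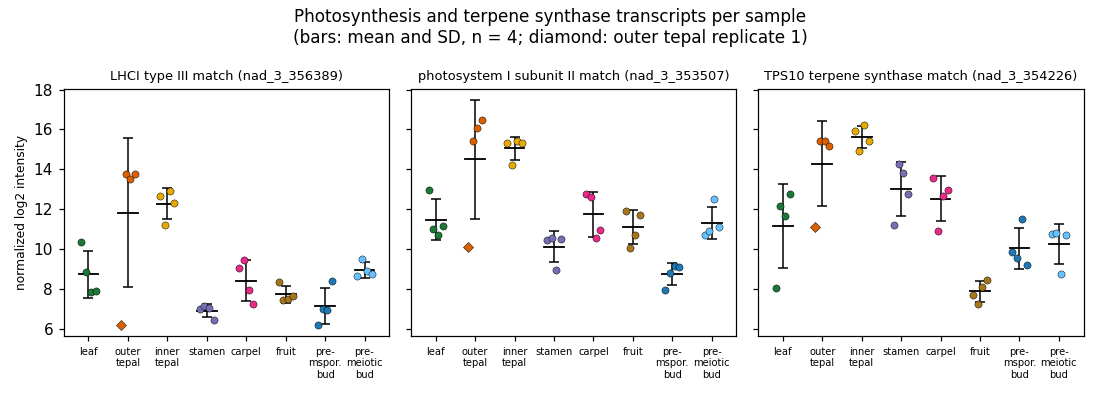
Normalized log2 intensity (vertical axis) of 3 photosynthesis and terpene synthase transcripts in the 8 tissues, with samples as points, the mean and standard deviation of 4 samples as bars, and outer tepal 1 as a diamond. In the LHCI type III match, outer tepal 1 lies at 6.22 and outer tepal 2 at 13.78.

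In inner tepals, TPS10, light-harvesting proteins, PISTILLATA and APETALA3 rose, and several histones and SPL transcripts fell. A cinnamyl-alcohol dehydrogenase match rose by 5.95 ± 0.47, PISTILLATA by 3.55 ± 0.4 and SEPALLATA1 by 2.02 ± 0.25 and 1.74 ± 0.21 (adjusted p from 3.5e-09 to 2.1e-06). Carotenoid and terpenoid transcripts shifted up (adjusted p = 1.7e-04, and adjusted p = 0.304 with an estimated correlation). TPS10 (4.47 ± 0.63), the second myrcene/ocimene synthase (4.39 ± 0.55) and 9-cis-epoxycarotenoid dioxygenase of abscisic acid synthesis (1.49 ± 0.32) were among the 10 of 15 measured members that rose, beside 0 that fell (11 and 1 adjusted over the list alone, median 0.66). Photosynthesis shifted up (adjusted p = 0.00462, and adjusted p = 0.411 with an estimated correlation). LHB1B1 (4.4 ± 0.86), the LHCI type III protein (3.55 ± 0.76), photosystem I subunit II (3.47 ± 0.68) and ferredoxin (2.43 ± 0.51) were among the 9 of 19 measured members that rose, beside 0 that fell (9 and 0 adjusted over the list alone, median 0.47). Cell division shifted down (adjusted p = 9.8e-10, and adjusted p = 0.318 with an estimated correlation). Histones H2B (-4.18 ± 0.5), H4 (-3.76 ± 0.51), H2A (-3.71 ± 0.52) and H3 (-3.54 ± 0.52) were among the 51 of 95 measured members that fell, beside 3 that rose (58 and 4 adjusted over the list alone, median -0.42).

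Ribosomal proteins shifted down in inner tepals (adjusted p = 5.0e-05, and adjusted p = 0.71 with an estimated correlation). RPL36aB (-1.73 ± 0.3) and RPS4D (-1.34 ± 0.34) were among the 63 of 123 measured members that fell, beside 16 that rose (66 and 16 adjusted over the list alone, median -0.48), and the L35 family member rose (1.38 ± 0.22). APETALA3 (1.62 ± 0.24 and 1.21 ± 0.28), APETALA2 (0.39 ± 0.15), the YABBY match nad_3_353063 (1.08 ± 0.25) and stress enhanced protein 1 (1.96 ± 0.31) rose (adjusted p from 1.5e-05 to 0.039). A group of 6 SPL transcripts fell, from -1.89 ± 0.44 to -0.51 ± 0.18, with SPL12 the lowest and SPL9 the highest, and AINTEGUMENTA fell (-0.28 ± 0.09), with adjusted p from 1.8e-06 to 0.034. Protodermal factor 1, a gene of the outer cell layer (-4.32 ± 0.68), and a cytochrome P450 (-3.91 ± 0.79) fell (adjusted p from 2.6e-05 to 4.0e-04). These 2, AINTEGUMENTA and the SPL transcript nad_3_354009 were each well above background in 1 of 4 inner tepals, so that the size of their falls is uncertain. The plant defensin PDF2.2 fell, with no size given because 0 of 4 inner tepals were well above background. In total 1787 transcripts differed, 918 higher and 869 lower, and 27 of 27 transcripts named only as list members had all 4 samples on the stated side. With log ratios the count was 786.

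Against outer tepals, no transcript passed in inner tepals: limma called 0 of 5016, with 360 at an unadjusted p under 0.05. The carotenoid and terpenoid list shifted up (adjusted p = 0.0209, and adjusted p = 0.408 with an estimated correlation), with a median of 0.17 over 15 measured members. Cell division (adjusted p = 0.046, and adjusted p = 0.814 with an estimated correlation), ribosomal proteins (adjusted p = 0.00196, and adjusted p = 0.814 with an estimated correlation) and heat shock and chaperones (adjusted p = 0.0134, and adjusted p = 0.579 with an estimated correlation) shifted down, with medians of -0.02, -0.13 and -0.13. In these 4 lists 0 members passed alone, and 0 adjusted over the list alone. Fits to the deposited values and with the replicate, slide or scan day block also called 0. The count was 1 without outer tepal 1, inner tepal 3 or normalization between arrays, and 68 without inner tepal 4. It was 1 without outer tepal 1 and pre-meiotic bud 3, and 273 (188 higher, 85 lower) without outer tepal 3 and inner tepal 4. In simulated data with this design and 200 of 5016 transcripts changed, 72% of changes of 1 log2 unit and 96% of 2 were called. This need not hold where fewer transcripts change or for samples nearer another tissue.

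In stamens, AGAMOUS, PISTILLATA and APETALA3 rose, and several histones and SPL transcripts fell. AGAMOUS rose by 3.21 ± 0.6, PISTILLATA by 2.48 ± 0.4, APETALA3 by 1.91 ± 0.24 and 0.92 ± 0.28, and SEPALLATA1 by 0.65 ± 0.21 (adjusted p from 3.9e-06 to 0.025). Starch and sucrose transcripts shifted up (adjusted p = 0.0054, and adjusted p = 0.318 with an estimated correlation). Starch phosphorylase (1.86 ± 0.24) and 2 small subunits of the starch synthesis enzyme APS1 (1.28 ± 0.26 and 1.26 ± 0.24) were among the 8 of 22 measured members that rose, beside 2 that fell (9 and 2 adjusted over the list alone, median 0.21). Cell division shifted down (adjusted p = 7.9e-09, and adjusted p = 0.318 with an estimated correlation). Histones H4 (-3.27 ± 0.34), H3 (-3.11 ± 0.52), H2B (-2.92 ± 0.39) and H2A (-2.87 ± 0.38) were among the 39 of 95 measured members that fell, beside 5 that rose (47 and 8 adjusted over the list alone, median -0.39). Lipid transfer, cutin and wax shifted down (adjusted p = 0.0054, and adjusted p = 0.441 with an estimated correlation). A GDSL lipase (-2.51 ± 0.49, well above background in 1 of 4 stamens) and 3 lipid transfer proteins (from -2.18 ± 0.61 to -1.45 ± 0.28) were among the 7 of 31 measured members that fell, beside 0 that rose (8 and 0 adjusted over the list alone, median -0.33).

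The cell wall list shifted down in stamens (adjusted p = 0.0342, and adjusted p = 0.557 with an estimated correlation). A family 1 glycosyl hydrolase (-2.3 ± 0.56) and a laccase (-1.53 ± 0.46) were among the 12 of 66 measured members that fell, beside 2 that rose (12 and 2 adjusted over the list alone, median -0.15). Defence and wounding shifted down (adjusted p = 0.00899, and adjusted p = 0.318 with an estimated correlation). Thaumatin (-3.03 ± 0.68) was among the 9 of 54 measured members that fell, beside 2 that rose (9 and 2 adjusted over the list alone, median -0.27), and cystatin, an inhibitor of cysteine proteases, rose (1.7 ± 0.42). Ribosomal proteins shifted down (adjusted p = 0.0172, and adjusted p = 0.82 with an estimated correlation). RPL36aB (-0.85 ± 0.3) was among the 8 of 123 measured members that fell, beside 2 that rose (0 and 2 adjusted over the list alone, median -0.16). A set of 6 SPL transcripts fell, from -2.07 ± 0.23 to -0.56 ± 0.17 (adjusted p from 6.9e-07 to 0.017; nad_3_358481 was well above background in 2 of 4 stamens), as did AGL6 (-1.04 ± 0.35), APETALA1 (-0.55 ± 0.17) and the auxin-responsive protein IAA11 (-2.52 ± 0.41), with adjusted p from 1.0e-04 to 0.034. The pollen, tapetum and anther wall list did not pass in stamens or in any of the 13 comparisons, with a lowest adjusted p of 0.0649, in young fruits. In total 1112 transcripts differed, 542 higher and 570 lower, and 33 of 33 transcripts named only as list members had all 4 samples on the stated side. With log ratios the count was 235.

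Compared with inner tepals alone, stamens had higher AGAMOUS (4.08 ± 0.78, limma adjusted p = 0.0028) and lower LHB1B1 and TPS10. The photosynthesis list shifted down (adjusted p = 1.9e-04, and adjusted p = 0.318 with an estimated correlation). The LHCI type III protein (-5.23 ± 0.99), LHB1B1 (-5.22 ± 1.12), photosystem I subunit II (-4.79 ± 0.89) and ferredoxin (-3.06 ± 0.66) were among the 8 of 19 measured members that fell, beside 0 that rose (8 and 0 adjusted over the list alone, median -0.39). Carotenoid and terpenoid transcripts shifted down (adjusted p = 0.0016, and adjusted p = 0.318 with an estimated correlation). TPS10 (-2.91 ± 0.82), the second myrcene/ocimene synthase (-3.06 ± 0.71) and 9-cis-epoxycarotenoid dioxygenase (-1.59 ± 0.42) were among the 4 of 15 measured members that fell, beside 0 that rose (6 and 0 adjusted over the list alone, median -0.38). The tubulin TUB1 (2.32 ± 0.46) and histone H3.2 (2.28 ± 0.51) rose (adjusted p from 0.0046 to 0.0078). Stress enhanced protein 1 (-2.25 ± 0.4), AGL6 (-1.46 ± 0.46), SEPALLATA1 (-1.21 ± 0.33 and -0.96 ± 0.27), SPL9 (-0.77 ± 0.24) and APETALA2 (-0.63 ± 0.19, well above background in 2 of 4 stamens) were lower (adjusted p from 0.0021 to 0.049).

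Defence and wounding shifted down from inner tepal to stamen (adjusted p = 0.0349, and adjusted p = 0.391 with an estimated correlation). A leucine-rich repeat protein (-1.07 ± 0.26) and a TIR-NBS-LRR protein (-0.72 ± 0.19) were among the 5 of 54 measured members that fell, beside 0 that rose (5 and 0 adjusted over the list alone, median -0.17). Heat shock and chaperones shifted up (adjusted p = 0.0342, and adjusted p = 0.651 with an estimated correlation). HSC70-5 (0.92 ± 0.25) and a mitochondrial HSP70 (0.79 ± 0.25) were the 2 of 70 measured members that rose, beside 1 that fell (1 and 1 adjusted over the list alone, median 0.17), and a DnaJ-related protein fell (-1.1 ± 0.26). The ribosomal list shifted up with a median of 0.25 (adjusted p = 0.0188, and adjusted p = 0.82 with an estimated correlation), yet each member that passed alone fell, 9 of 123 and 9 adjusted over the list alone. S9 (-1.25 ± 0.25), L3 (-1.24 ± 0.23), the plastid protein PSRP-3 (-1.2 ± 0.26) and S1 (-1.09 ± 0.28) were among those 9. In total 378 transcripts differed, 138 higher and 240 lower, and 17 of 17 transcripts named only as list members had all 4 samples on the stated side. The count was 60 without inner tepal 1, 138 without inner tepal 3, 592 without inner tepal 4, 118 without stamen 1 and 208 without stamen 3. It was 584 without outer tepal 3 and inner tepal 4, 229 with the slide block, 41 with only these 2 tissues in the fit and 0 with log ratios. The scanner software's processed signals gave 105 higher and 104 lower, and quantile normalization over all channels 155 and 155.

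Carpels differed least from the mean of the other tissues. AGAMOUS rose by 2.67 ± 0.6 and SPL9 by 0.74 ± 0.18, while the SPL transcript nad_3_358481 fell (-0.71 ± 0.17), with adjusted p from 0.017 to 0.031. An auxin-responsive GH3 protein (1.3 ± 0.27) and the vacuolar membrane channel delta-TIP (0.95 ± 0.24) rose (adjusted p from 0.011 to 0.035). A late embryogenesis abundant protein (-2.9 ± 0.69) and the plastid ribosomal protein PSRP-3 (-0.75 ± 0.2) fell (adjusted p from 0.024 to 0.045). The flavonoid and phenylpropanoid list shifted down (adjusted p = 0.00846, and adjusted p = 0.22 with an estimated correlation). Leucoanthocyanidin dioxygenases of anthocyanin synthesis (-2.42 ± 0.53 and -2.08 ± 0.54) were the 2 of 22 measured members that fell, beside 0 that rose (4 and 2 adjusted over the list alone, median -0.13). Defence and wounding shifted up (adjusted p = 0.046, and adjusted p = 0.413 with an estimated correlation). A lipid transfer protein (1.85 ± 0.49), a leucine-rich repeat protein (1.17 ± 0.25) and a TIR-NBS-LRR protein (0.61 ± 0.15) were among the 4 of 54 measured members that rose, beside 0 that fell (6 and 0 adjusted over the list alone, median 0.04).

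Cell division in carpels shifted up (adjusted p = 0.01, and adjusted p = 0.71 with an estimated correlation). A histone H4 (1.19 ± 0.3) was the 1 of 95 measured members that rose, beside 0 that fell (0 and 0 adjusted over the list alone, median 0.12). Ribosomal proteins shifted up (adjusted p = 0.00205, and adjusted p = 0.814 with an estimated correlation). RPL34B (0.64 ± 0.17) was the 1 of 123 measured members that rose, beside 1 that fell (0 and 0 adjusted over the list alone, median 0.23). Heat shock and chaperones shifted up (adjusted p = 0.0228, and adjusted p = 0.618 with an estimated correlation), with a median of 0.14 and 0 of 70 measured members past the threshold, over all transcripts or adjusted over the list alone. In total 123 transcripts differed, 82 higher and 41 lower, and 11 of 11 transcripts named only as list members had all 4 samples on the stated side. The count was 31 without carpel 1, 53 without carpel 2, 29 without carpel 3, 33 without carpel 4 and 214 without outer tepal 1 and pre-meiotic bud 3. With the tissue labels permuted, 5 of 100 orders gave a count as large as 123, so that chance is not excluded. The count was 59 with the scanner software's processed signals, 76 with median centring, 61 without the correlation within arrays and 6 with log ratios.

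Against stamens, several histones rose in carpels, and PISTILLATA and APETALA3 fell. Cell division shifted up (adjusted p = 5.7e-09, and adjusted p = 0.318 with an estimated correlation). Histones H3 (3.96 ± 0.67), H4 (3.79 ± 0.62), H2B (3.76 ± 0.65) and H2A (3.71 ± 0.5) were among the 33 of 95 measured members that rose, beside 2 that fell (43 and 4 adjusted over the list alone, median 0.39). Carpel 2 lay above the other carpels by 1.31 in H3, 1.1 in H4 and 1.94 in H2A. PISTILLATA (-3.25 ± 0.52) and APETALA3 (-2.08 ± 0.31) fell, AGL6 rose (1.92 ± 0.46), and 4 SPL transcripts rose, from 1.13 ± 0.25 to 2.47 ± 0.3 (adjusted p from 7.5e-06 to 0.0058). A 4-aminobutyrate aminotransferase, which breaks down GABA (5.34 ± 1.04), OPR2 (5.34 ± 1.03) and thaumatin (4.6 ± 0.88) rose (adjusted p from 0.001 to 0.0013). Leucoanthocyanidin dioxygenase (-4.03 ± 0.69), fructose-1,6-bisphosphatase (-3.1 ± 0.37) and aconitase (-2.29 ± 0.36) fell (adjusted p from 7.5e-06 to 3.7e-04). Defence and wounding shifted up (adjusted p = 0.00196, and adjusted p = 0.318 with an estimated correlation), with thaumatin among the 10 of 54 measured members that rose, beside 1 that fell (12 and 1 adjusted over the list alone, median 0.36).

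Lipid transfer, cutin and wax transcripts shifted up in carpels against stamens (adjusted p = 0.0349, and adjusted p = 0.617 with an estimated correlation). A group of 3 lipid transfer proteins (from 2.76 ± 0.8 to 3.71 ± 1.11) and a GDSL lipase (2.34 ± 0.64, well above background in 1 of 4 stamens) were among the 7 of 31 measured members that rose, beside 0 that fell (8 and 1 adjusted over the list alone, median 0.36). Ribosomal proteins shifted up (adjusted p = 5.0e-04, and adjusted p = 0.769 with an estimated correlation). RPL13B (1.04 ± 0.34) and RPS23B (0.95 ± 0.31) were among the 7 of 123 measured members that rose, beside 3 that fell (0 and 3 adjusted over the list alone, median 0.37), and the plastid-like S6 member fell (-0.87 ± 0.21). Starch and sucrose shifted down (adjusted p = 0.00696, and adjusted p = 0.318 with an estimated correlation). Starch phosphorylase (-1.88 ± 0.32) and 2 APS1 transcripts (-1.64 ± 0.34 and -1.48 ± 0.31) were among the 8 of 22 measured members that fell, beside 4 that rose (9 and 4 adjusted over the list alone, median -0.28). In total 686 transcripts differed, 369 higher and 317 lower, and 18 of 18 transcripts named only as list members had all 4 samples on the stated side. The count was 440 without stamen 3, 372 without carpel 2, 411 without carpel 3 and 34 with log ratios.

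In young fruits, PISTILLATA, APETALA3, SPL transcripts and TPS10 fell, and 3 sucrose synthases rose. The floral list shifted down (adjusted p = 8.5e-08, and adjusted p = 0.22 with an estimated correlation). PISTILLATA (-3.94 ± 0.4), the YABBY match nad_3_353063 (-3.08 ± 0.25), APETALA3 (-1.93 ± 0.24 and -0.85 ± 0.28), APETALA1 (-1.28 ± 0.17) and 6 SPL transcripts (from -2.19 ± 0.44 to -0.64 ± 0.17) were among the 12 of 23 measured members that fell, beside 0 that rose (12 and 0 adjusted over the list alone, median -0.5). Carotenoid and terpenoid transcripts shifted down (adjusted p = 0.00267, and adjusted p = 0.318 with an estimated correlation). TPS10 (-4.62 ± 0.63), 1-deoxyxylulose 5-phosphate synthase, the first step of plastid isoprenoid synthesis (-3.59 ± 0.9), and a copper chaperone relative, matched by a word (-0.93 ± 0.28), were among the 7 of 15 measured members that fell, beside 0 that rose (9 and 1 adjusted over the list alone, median -0.41). Starch and sucrose shifted up (adjusted p = 0.0201, and adjusted p = 0.349 with an estimated correlation). A group of 3 sucrose synthases (from 2.39 ± 0.28 to 2.64 ± 0.27) and APS1 (1.6 ± 0.26) were among the 9 of 22 measured members that rose, beside 2 that fell (9 and 5 adjusted over the list alone, median 0.12). Ribosomal proteins shifted up (adjusted p = 7.9e-09, and adjusted p = 0.553 with an estimated correlation). RPL31C (0.96 ± 0.2) and RPL36B (0.88 ± 0.31) were among the 24 of 123 measured members that rose, beside 1 that fell (26 and 2 adjusted over the list alone, median 0.34). Young fruit 3 lay lower in these, on the stated side only for RPL31C, at 11.21 and 11.25, with the others from 12.41 to 12.48 and 12.88 to 13.08.

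Heat shock and chaperones shifted up in young fruits (adjusted p = 0.0137, and adjusted p = 0.579 with an estimated correlation). The chaperonins CPN10 (1.23 ± 0.2) and CPN21 (0.86 ± 0.26) were among the 8 of 70 measured members that rose, beside 2 that fell (8 and 2 adjusted over the list alone, median 0.19), and the plastid division protein ARC6 fell (-0.85 ± 0.18). Defence and wounding shifted down (adjusted p = 8.8e-04, and adjusted p = 0.304 with an estimated correlation). Cystatin (-3.59 ± 0.42), a lipid transfer protein (-2.45 ± 0.5) and the lipoxygenase LOX2 of jasmonate synthesis (-2.18 ± 0.69) were among the 12 of 54 measured members that fell, beside 0 that rose (17 and 1 adjusted over the list alone, median -0.37). The cell wall list shifted down (adjusted p = 0.0349, and adjusted p = 0.558 with an estimated correlation). A family 1 glycosyl hydrolase (-1.9 ± 0.24, well above background in 1 of 4 young fruits) and a pectin methylesterase (-1.84 ± 0.52) were among the 9 of 66 measured members that fell, beside 3 that rose (9 and 3 adjusted over the list alone, median -0.22), and a laccase rose (2.8 ± 0.46). In total 920 transcripts differed, 419 higher and 501 lower, and 27 of 32 transcripts named only as list members had all 4 samples on the stated side, with young fruit 3 off it in the other 5. The count was 521 without young fruit 1 and 234 with log ratios. Median centring gave 442 higher and 323 lower, and no normalization between arrays 299 and 587.

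From carpel to young fruit, PISTILLATA, APETALA3, TPS10 and cystatin fell, and leucoanthocyanidin dioxygenases and APS1 rose. The floral list shifted down (adjusted p = 3.1e-07, and adjusted p = 0.233 with an estimated correlation). The YABBY match nad_3_353063 (-2.47 ± 0.32), PISTILLATA (-2.36 ± 0.52), APETALA3 (-1.29 ± 0.31), APETALA1 (-0.78 ± 0.23) and 5 SPL transcripts (from -2.43 ± 0.3 to -1.29 ± 0.25) were the 9 of 23 measured members that fell, beside 0 that rose (10 and 0 adjusted over the list alone, median -0.49). Flavonoid and phenylpropanoid transcripts shifted up (adjusted p = 0.00222, and adjusted p = 0.22 with an estimated correlation). Leucoanthocyanidin dioxygenases (3.13 ± 0.7 and 2.91 ± 0.69) and dihydroflavonol reductase (2.83 ± 0.29) of anthocyanin synthesis were among the 6 of 22 measured members that rose, beside 1 that fell (8 and 1 adjusted over the list alone, median 0.16), and quercetin 3-O-methyltransferase fell (-5.22 ± 0.79). Starch and sucrose shifted up (adjusted p = 0.0054, and adjusted p = 0.318 with an estimated correlation). APS1 (1.92 ± 0.34), a sucrose synthase (1.69 ± 0.35) and starch branching enzyme (1.57 ± 0.34) were among the 9 of 22 measured members that rose, beside 1 that fell (10 and 1 adjusted over the list alone, median 0.14).

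Carotenoid and terpenoid transcripts shifted down from carpel to fruit (adjusted p = 0.00645, and adjusted p = 0.349 with an estimated correlation). TPS10 (-4.49 ± 0.82), 1-deoxyxylulose 5-phosphate synthase (-3.75 ± 1.18) and the second myrcene/ocimene synthase (-3.45 ± 0.71) were among the 4 of 15 measured members that fell, beside 0 that rose (6 and 0 adjusted over the list alone, median -0.25). Defence and wounding shifted down (adjusted p = 3.9e-05, and adjusted p = 0.22 with an estimated correlation). Cystatin (-2.97 ± 0.55) and 3 lipid transfer proteins (from -3.67 ± 1.11 to -2.23 ± 0.64) were among the 9 of 54 measured members that fell, beside 0 that rose (15 and 0 adjusted over the list alone, median -0.4). The cell wall list shifted down (adjusted p = 0.0472, and adjusted p = 0.579 with an estimated correlation). A pectinesterase (-2.1 ± 0.53) and a polygalacturonase (-1.8 ± 0.53) were among the 13 of 66 measured members that fell, beside 2 that rose (17 and 4 adjusted over the list alone, median -0.08). Ribosomal proteins shifted up (adjusted p = 0.00776, and adjusted p = 0.82 with an estimated correlation). L3 (1.02 ± 0.23) and PSRP-3 (0.88 ± 0.26) were among the 8 of 123 measured members that rose, beside 1 that fell (8 and 1 adjusted over the list alone, median 0.1). The seed, embryo and storage list did not pass here or in any comparison, with a lowest adjusted p of 0.065 in this one.

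Between young fruits and carpels 422 transcripts differed, 176 higher and 246 lower, and 27 of 27 transcripts named only as list members had all 4 samples on the stated side. The count was 248 without carpel 1, 246 without carpel 3 and 174 without young fruit 1. It was 276 with median centring, 268 without the correlation within arrays and 53 with log ratios, and quantile normalization over all channels gave 184 higher and 156 lower.

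In pre-microsporangial buds, several histones, 7 SPL transcripts and PDF2.2 rose, and LHB1B1 and TPS10 fell. Cell division shifted up (adjusted p = 1.4e-07, and adjusted p = 0.349 with an estimated correlation). Histones H3 (3.48 ± 0.52), H2B (3.1 ± 0.5) and H4 (3.07 ± 0.51) and a D3-type cyclin, of entry into DNA replication (3.3 ± 0.26), were among the 48 of 95 measured members that rose, beside 4 that fell (51 and 4 adjusted over the list alone, median 0.5). PDF2.2 (5.47 ± 1.05) and the wax synthesis gene CER1 (3.65 ± 0.53) rose (adjusted p from 7.1e-06 to 2.5e-04). The floral list shifted up (adjusted p = 0.00196, and adjusted p = 0.349 with an estimated correlation). A group of 7 SPL transcripts (from 0.5 ± 0.09 to 2.91 ± 0.44), APETALA1 (1.0 ± 0.17), the PISTILLATA match nad_3_353295 (0.74 ± 0.2) and AINTEGUMENTA (0.51 ± 0.09) were among the 11 of 23 measured members that rose, beside 1 that fell (11 and 1 adjusted over the list alone, median 0.22), and stress enhanced protein 1 fell (-1.08 ± 0.31). Photosynthesis shifted down (adjusted p = 0.00653, and adjusted p = 0.441 with an estimated correlation). LHB1B1 (-3.37 ± 0.86), photosystem I subunit II (-3.36 ± 0.68) and ferredoxin (-2.0 ± 0.51) were among the 11 of 19 measured members that fell, beside 0 that rose (11 and 0 adjusted over the list alone, median -0.7).

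Carotenoid and terpenoid transcripts shifted down in pre-microsporangial buds (adjusted p = 0.0137, and adjusted p = 0.365 with an estimated correlation). TPS10 (-2.22 ± 0.63) and farnesyl pyrophosphate synthetase FPS1 (-0.85 ± 0.17) were among the 8 of 15 measured members that fell, beside 0 that rose (9 and 0 adjusted over the list alone, median -0.41). Starch and sucrose shifted down (adjusted p = 0.0137, and adjusted p = 0.339 with an estimated correlation). Starch branching enzyme (-1.13 ± 0.26) and starch phosphorylase (-0.89 ± 0.24) were among the 9 of 22 measured members that fell, beside 0 that rose (9 and 0 adjusted over the list alone, median -0.26). In total 1776 transcripts differed, 908 higher and 868 lower, and 26 of 26 transcripts named only as list members had all 4 samples on the stated side. Pre-microsporangial bud 2 stood apart, with a correlation of 0.887 with the others, 43.85 on the second component against 5.693 to 11.88, and 52% of probes well above background. The count was 1383 without it and 812 with log ratios.

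In pre-meiotic buds, a late embryogenesis abundant transcript and 5 SPL transcripts rose, and starch phosphorylase fell. The late embryogenesis abundant protein rose by 5.09 ± 0.69 and alpha-mannosidase by 1.39 ± 0.2 (adjusted p from 2.1e-05 to 3.2e-05). The floral list shifted up (adjusted p = 0.00353, and adjusted p = 0.365 with an estimated correlation). A group of 5 SPL transcripts (from 0.6 ± 0.19 to 1.69 ± 0.44), the PISTILLATA match nad_3_353295 (0.83 ± 0.2), APETALA1 (0.76 ± 0.17) and the AINTEGUMENTA relative nad_3_356131 (0.72 ± 0.19) were the 8 of 23 measured members that rose, beside 0 that fell (8 and 0 adjusted over the list alone, median 0.22). Pre-meiotic bud 3 was off the stated side in 6 of these 8, with SPL12 at 6.97, against 11.35, 11.8 and 10.87. Starch and sucrose shifted down (adjusted p = 0.0021, and adjusted p = 0.318 with an estimated correlation). Starch phosphorylase (-0.95 ± 0.24), APS1 (-0.9 ± 0.26) and a sucrose synthase (-0.79 ± 0.27) were among the 8 of 22 measured members that fell, beside 0 that rose (11 and 0 adjusted over the list alone, median -0.38). Photosynthesis shifted down (adjusted p = 0.0326, and adjusted p = 0.579 with an estimated correlation). A plastocyanin-like protein (-0.85 ± 0.24) and OHP2 (-0.38 ± 0.13) were among the 3 of 19 measured members that fell, beside 1 that rose (6 and 1 adjusted over the list alone, median -0.22), and the RuBisCO small chain 1B rose (1.25 ± 0.36).

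For pre-meiotic buds 949 transcripts differed, 488 higher and 461 lower, and 8 of 16 transcripts named only as list members had all 4 samples on the stated side. The count was 612 without pre-meiotic bud 1, 562 without pre-meiotic bud 2, 625 with median centring and 271 with log ratios.

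From the pre-microsporangial to the pre-meiotic bud, several histones fell, and the cell division list shifted down (adjusted p = 8.4e-07, and adjusted p = 0.365 with an estimated correlation). Histones H3 (-2.76 ± 0.67), H2A (-2.47 ± 0.68), H4 (-2.29 ± 0.62) and H2B (-2.14 ± 0.65) were among the 22 of 95 measured members that fell, beside 1 that rose (34 and 3 adjusted over the list alone, median -0.36). Protodermal factor 1 (-2.08 ± 0.58), the auxin carrier PIN3 (-2.02 ± 0.47) and the DNA clamp PCNA2 (-1.96 ± 0.48) fell (adjusted p from 0.0093 to 0.026). Glutamate decarboxylase, which makes GABA (1.9 ± 0.58), and the purine permease PUP1 (1.37 ± 0.4) rose (adjusted p from 0.035 to 0.042). YABBY1 (-0.61 ± 0.13), AINTEGUMENTA (-0.47 ± 0.12) and 4 SPL transcripts (from -1.21 ± 0.3 to -0.37 ± 0.11) fell, and the AINTEGUMENTA relative nad_3_356131 rose (0.8 ± 0.25), with adjusted p from 0.0042 to 0.043. The auxin list did not pass here or in any comparison, and its lowest adjusted p, 0.0837, was in this one.

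Between the buds 404 transcripts differed, 190 higher and 214 lower, and 7 of 8 transcripts named only as list members had all 4 samples on the stated side. The count was 150 without pre-microsporangial bud 1, 230 without pre-microsporangial bud 2, 653 without pre-microsporangial bud 3, 204 without pre-microsporangial bud 4 and 239 without pre-meiotic bud 3. It was 259 without outer tepal 1 and pre-meiotic bud 3 together, 199 with median centring, 15 with only these 2 tissues in the fit and 0 with log ratios. No normalization between arrays gave 96 higher and 71 lower.

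Over all 182 pairs of a list and a comparison, 61 passed at the preset correlation between genes and 0 with an estimated correlation. Cell division, DNA replication and chromatin transcripts passed in 9 comparisons at the preset correlation, up in leaves, carpels and pre-microsporangial buds and down in tepals and stamens. With permuted tissue labels at least 1 pair passed in 99 other orders, and 66 was the highest.

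**Figure D5:**
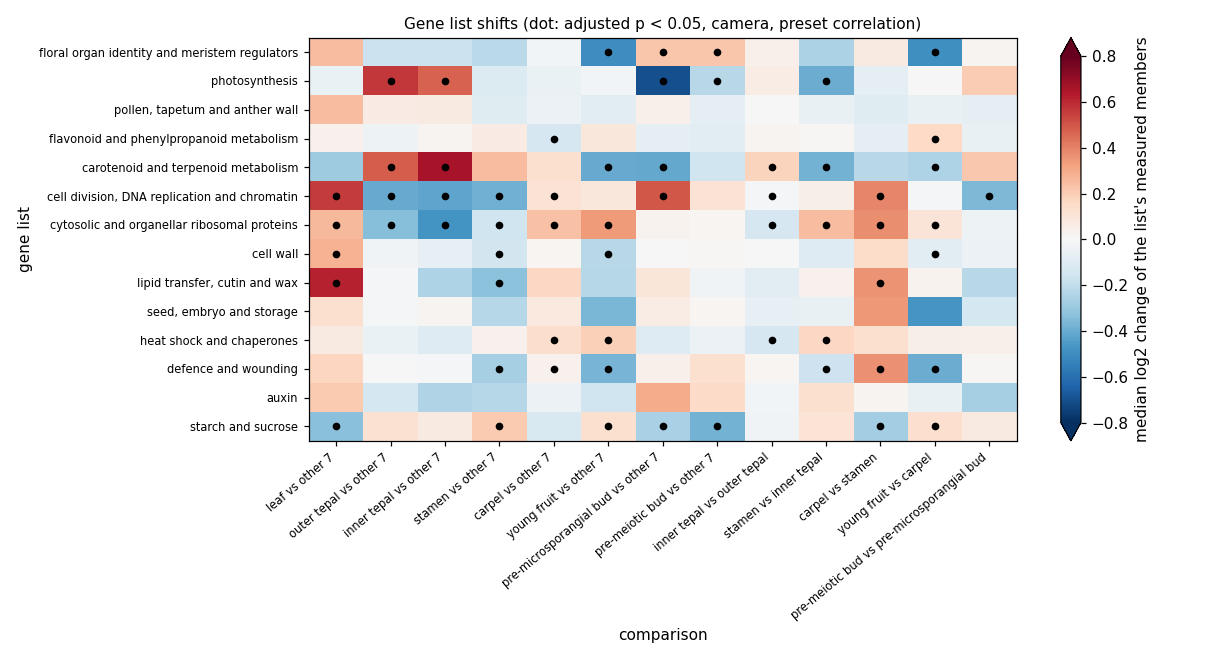
Median log2 change (colour scale) of the measured members of 14 gene lists (rows) in 13 comparisons (columns), where dots mark an adjusted p under 0.05 with the preset correlation. The cell division list had medians of 0.56 in leaves and -0.42 in inner tepals.

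Replicates were spread over 9 slides and 4 scan days. With the replicate block, which treats equal replicate numbers as paired, the counts were 1388 in leaves, 1235 in outer tepals, 1896 in inner tepals, 1222 in stamens, 161 in carpels, 1013 in young fruits, 1879 in pre-microsporangial buds and 1010 in pre-meiotic buds. For the pairs the replicate block gave 0 for inner against outer tepal, 434 for stamen against inner tepal, 806 for carpel against stamen, 473 for young fruit against carpel and 473 for the buds. With slide as a block the same 13 counts were 1141, 907, 1621, 906, 115, 725, 1556, 946, 0, 229, 499, 337 and 438. Scan day as a block, an alternative chosen after the data were seen, gave 1262, 1177, 1847, 1184, 121, 903, 1846, 965, 0, 401, 726, 405 and 443. The first and second scan days held 1 sample of each tissue, too few for a test. Of 10951 calls over all comparisons, 10691 had the same direction on the first day, 10673 on the second and 10902 in the 14 samples of the third, and of 61 list shifts 58, 60 and 59, with 2 of 4 for outer tepals on the first day and 2 of 4 for inner against outer tepal on the third. The calls were made with these same samples, so that this is no separate test. A fit to the third day alone, with 1 or 2 samples of a tissue, gave 13 counts of 4, 215, 203, 198, 0, 8, 332, 72, 0, 16, 50, 4 and 0. The fourth day held 2 samples and a slide at most 4, too few for a test.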

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

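The tests of swapped or exchanged labels, stamen signal, scan day shift, dim channel and bud stage were chosen only after the results were seen, and the tests of inner tepal signal, of scan day or dye in the tepal split and of split labels were written before.

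Single samples that lay far from the other 3 of their tissue, by Dixon's test of a group of 4, are given as the normalized log2 value minus the mean of the other 3. Such a test marks about 1 in 20 groups by chance, and here it marked 57 of 565 groups of named transcripts (10.1%) and 2 of 24 groups of sample measures. Outer tepal 1 had 26.6 percentage points more probes well above background than the mean of the other outer tepals. Young fruit 1 had a median signal 301 above the mean of the other young fruits.

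Leaf 1 had OPR2 0.757, a cytochrome P450 0.993 and a sucrose synthase 0.286. Outer tepal 3 had PISTILLATA (nad_3_353295) -0.391. Outer tepal 1 had photosystem I subunit II -5.88, TPS10 -4.23, the LHCI type III protein -7.47, a dynamin -0.901 and LHB1B1 -6.12. Outer tepal 4 had the SPL transcript nad_3_358481 0.209. Inner tepal 1 had TUB1 -0.755. Inner tepal 2 had a lipid transfer protein -1.93 and photosystem I subunit II -1.16. Inner tepal 4 had AGL6 1.4, a pectin methylesterase -2.64 and a cinnamyl-alcohol dehydrogenase -1.74.

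Stamen 3 had photosystem I subunit II -1.54, fructose-1,6-bisphosphatase 1.47, RPS10C -0.485, a family 1 glycosyl hydrolase 0.467 and SEPALLATA1 (nad_3_356714) 1.06. Stamen 1 had a cytochrome P450 -3.11. Stamen 2 had AGAMOUS -2, a leucine-rich repeat protein 1, APETALA1 -0.59 and APETALA3 -1.21. Carpel 2 had dihydroflavonol reductase 1.01, histone H3 1.31, RPS3C 0.672, cytochrome b5 0.857, cystatin -2.2, a GDSL lipase 1.29, histone H2A 1.94, histone H4 1.1 and leucoanthocyanidin dioxygenase 1.85. Carpel 4 had APG1 0.128 and delta-TIP 0.352. Carpel 1 had a pectinesterase -1.03 and an auxin-responsive GH3 protein 2.39. Carpel 3 had L3 -0.639.

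Young fruit 3 had RPL31C -1.24, RPL36aB -2.13, RPL36B -1.76, APETALA1 -0.196, a laccase -2.41, CPN21 -1.48, AINTEGUMENTA -0.157 and RPS3A -1.19. Young fruit 1 had quercetin 3-O-methyltransferase 1.18. Young fruit 2 had APS1 -1.52. Pre-microsporangial bud 3 had YABBY1 -0.588. Pre-microsporangial bud 4 had stress enhanced protein 1 0.807. Pre-microsporangial bud 1 had a MAR-binding protein -0.717. Pre-meiotic bud 2 had SEPALLATA1 (nad_3_353945) -0.571.

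Pre-meiotic bud 3 had AGL6 -1.52 and an aspartyl protease -3.6. Pre-meiotic bud 1 had APETALA1 0.846.

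Outer tepal 1 stood apart from the other outer tepals toward the stamens. For stamen RNA in the library, or a stamen sample under its label, the slope of its deviation on the stamen minus outer tepal difference was 0.549, but this restates the correlation with stamens by which the library was found, so that it was left undecided. For swapped labels of outer tepal 1 and stamen 1 the slope of stamen 1 toward outer tepal was 0.0227, which argued against a swap. A shift shared by the first scan day was left undecided by a median correlation of 0.143, with 0.597 for stamen 1 alone. No biological explanation was tested, and whether the label or the RNA differs stays open.

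Pre-meiotic bud 3 stood apart from the other pre-meiotic buds. Inner tepal signal from the other channel of its array fitted by a margin of only 0.00651, with correlations of 0.491 toward inner tepal, 0.485 toward stamen and 0.401 toward outer tepal, so that it does not tell these organs apart. A dim channel was left undecided by 84.1% of probes well above background, not the lowest of the pre-meiotic buds, with a median signal of 138.2, the lowest (523.9, 233.3 and 218.8 in the others). A stage farther along, the biological explanation the design gives, had a slope of 0.285 and was left undecided. What sets this library apart stays open.

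The labels called 0 transcripts between inner and outer tepals, while the split with inner tepal 4 and outer tepal 3 exchanged called 506, 302 higher and 204 lower. For exchanged labels the smaller slope toward the other tepal was 0.507 and the other 0.674, but the hypothesis was found and tested on the same data, so that it was left undecided. Both samples were Cy3 on the third scan day, so day or dye could not line up with the split. The 553 calls with scan day as a block thus decide nothing. With the labels exchanged inner tepals had 2105 transcripts, outer tepals 1069 and stamen against inner tepal 729, and the top of the split held a cytochrome P450 (3.7, limma adjusted p = 9.0e-08), a pectin methylesterase (2.21) and HMG-CoA reductase 1 of sterol synthesis (2.65). No biological explanation was tested, and the labels were kept as given.

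The slopes in these tests were first computed with a correction for noise and then replaced by the plain slope, as the tests were worded, after the corrected values had been seen. The corrected form gave 0.941 for outer tepal 1, and -4.36, 13.7 and 6.14 for outer tepals 2 to 4, whose references hold outer tepal 1 and which are no longer compared. It gave 0.0218 for stamen 1, 0.704 for pre-meiotic bud 3, and 1.08 and 1.27 for outer tepal 3 and inner tepal 4. Compared with outer tepals 2 to 4, the corrected form had argued against stamen RNA in outer tepal 1, and it had fitted a stage farther along in pre-meiotic bud 3.

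In 100 permutations of the 32 tissue labels, the true labels included, 1 was as large for leaves (real value 1264, highest other 197), outer tepals (1130, 290), inner tepals (1787, 594) and stamens (1112, 283). The same held for young fruits (920, 326), pre-microsporangial buds (1776, 456), pre-meiotic buds (949, 10), any difference (3174, 410) and the median over tissue pairs (1039.5, 1). For carpels 5 of 100 were as large as the real 123, the highest 782, so that chance cannot be excluded. The list shifts had 4 of 100 as large as the real 61, the highest other 66, and 99 permutations above 0. The permutations ignore the replicate numbers. The 4 of 100 are fewer than 1 in 20. Yet 99 permutations called lists, for an untested cause, and 0 passed with an estimated correlation, so that chance stays open.

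In all 35 splits of the 8 samples of a pair, 1 was as large for carpel against stamen (real 686, highest other 2). The same held for young fruit against carpel (422, 65), the buds (404, 287) and stamen against inner tepal (378, 337). Free splits ignore replicate numbers, and samples of the same number correlated at 0.313 to 0.534 in the last pair. Exchanges within numbers are 8 per pair, with 1 as large and the highest other 1, 21, 63 and 12. This cannot reach 1 in 20, so that chance is not excluded for these pairs. For inner against outer tepal 35 of 35 were as large as the real 0, as any split must be, so that this says nothing of chance, and the highest other was 506. Splits that call 506, 337 or 287 transcripts point to a structure of the samples beside the labels.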

How the results depend on the processing

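No named transcript or list reversed its direction under the alternatives it was fitted with. The slide block could not be fitted for 19 of 448 named results nor the filter requiring all 4 samples for 3, and the lists were not followed in the fits of a pair alone or without 1 sample. The larger side of the calls changed in some comparisons: in young fruits from 419 higher and 501 lower to 442 and 323 with median centring and 581 and 466 with quantile normalization, and in pre-microsporangial buds from 908 and 868 to 683 and 896 with median centring and 1012 and 1114 with quantile normalization. Quantile normalization also changed it in stamens (713 higher, 578 lower), pre-meiotic buds (446, 539), carpel against stamen (367, 407) and young fruit against carpel (184, 156). The processed signals changed it in pre-meiotic buds (401, 475) and stamen against inner tepal (105, 104), median centring between the buds (105, 94), and no normalization between arrays in inner tepals (656, 757), pre-microsporangial buds (681, 683) and between the buds (96, 71). For the values below, the cause was not tested, except where fewer samples or arrays enter the fit by construction.

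With the processed signals of Feature Extraction carpels had 59 transcripts and stamen against inner tepal 209. Median centring in place of loess gave 76 for carpels, 625 for pre-meiotic buds, 200 for stamen against inner tepal, 276 for young fruit against carpel and 199 between the buds. Without normalization between arrays 1 transcript differed between inner and outer tepals and 167 between the buds. Without the correlation within arrays the counts were 61 for carpels, 221 for stamen against inner tepal and 268 for young fruit against carpel. With the slide block stamen against inner tepal had 229.

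Log ratios of the 16 arrays compare only the 2 channels of an array by construction and lowered most counts: 599 in leaves, 264 in outer tepals, 786 in inner tepals, 235 in stamens, 6 in carpels, 234 in young fruits, 812 in pre-microsporangial buds and 271 in pre-meiotic buds. For pairs log ratios gave 0 for stamen against inner tepal, 34 for carpel against stamen, 53 for young fruit against carpel and 0 between the buds. Any difference among the 8 tissues then had 1525 transcripts, and the median over tissue pairs was 260.5. With only the samples of the 2 tissues in the fit, fewer samples by construction, stamen against inner tepal had 41 and the buds 15.

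Without outer tepal 1 and pre-meiotic bud 3 carpels had 214 transcripts, inner against outer tepal 1 and the buds 259. Without outer tepal 3 and inner tepal 4 outer tepals had 683, inner against outer tepal 273 and stamen against inner tepal 584. With an estimated correlation between genes 0 of the list shifts passed, against 61 with the preset one. Requiring all 4 samples, a stricter rule by construction, left 2870 transcripts well above background in pre-microsporangial buds.

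Leaving out 1 sample of the compared tissues at a time, and of no other tissue, gave ranges of 620 to 1088 for leaves, 646 to 1072 for outer tepals, 1260 to 1848 for inner tepals, 746 to 925 for stamens, 29 to 53 for carpels and 521 to 815 for young fruits. It gave 1383 to 1715 for pre-microsporangial buds and 562 to 849 for pre-meiotic buds. The ranges for pairs were 0 to 68 for inner against outer tepal, 60 to 592 for stamen against inner tepal, 372 to 667 for carpel against stamen, 174 to 454 for young fruit against carpel and 150 to 653 between the buds. Any difference among tissues ranged from 2966 to 3255, the median of pairs from 847 to 1104.5 and the list shifts from 54 to 68.

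Of the 448 named results 251 no longer passed with log ratios, 54 with median centring, 52 without the correlation within arrays, 46 with the processed signals, 39 without normalization between arrays, 23 with quantile normalization, 23 with the brightest probe, 18 without the filter, 15 without the dye covariate, 12 with the deposited table, 11 with the scan day block and 2 with the replicate block. These were 59 of 429 with the slide block, 56 of 150 with only the samples of a pair, 0 of 445 with the filter requiring all 4 samples, 19 without outer tepal 1 and pre-meiotic bud 3, and 21 without outer tepal 3 and inner tepal 4. Each named result was refitted without each sample of its tissues in turn, and 451 of these refits did not pass while 1941 did. Of the 61 list shifts 12 no longer passed with the slide block, 9 with log ratios, 9 with the brightest probe, 6 with median centring, 6 without normalization between arrays, and 1 to 4 in each other refit that was run. The share of probes well above background limits what can be seen of dim transcripts.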

Other observations

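Samples with the same replicate number in different tissues deviated from their tissue means alike more often than samples with different numbers. The mean correlation of these deviations was 0.115 for the same number on another array, 0.156 on the same array and -0.0389 for different numbers, and 23 of 32 samples correlated best with a sample of their own number. Between inner and outer tepals of the same number it ran from 0.212 to 0.685, and between stamens and inner tepals from 0.313 to 0.534. All samples of number 1 were scanned on the first day, on slides 1 and 2 and with Feature Extraction 9.1.3.1, and those of number 2 on the second day, on slides 3 and 4. Numbers 3 and 4 lay on different slides of the third day, but for 2 samples of number 3 on the fourth day, so that a shared number goes with a shared day and slides.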
